A study of Mus musculus with 4 samples.

How the data were processed

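Cells were taken from mesenteric lymph nodes of 15-day-old mice, from C57BL/6 animals (WT) and from animals that lack the Rorc enhancer named +7kb (KO), per the labels. Rorc encodes RORgt, the transcription factor that ILC3 need. Per the series' design text, dendritic cells were sorted as CD3-B220-CD11c+MHC-II+ and ILC3 as CD3-B220-CD11c-MHC-II+CCR6+, with 4 biological replicates per genotype told apart by antibody hashtags. Per the labels' protocols, both were sequenced from 10x Genomics 3' libraries, chemistry version 3, at a targeted median of 50000 reads per cell. The position of the deleted part is not given. Rorc counts were read as its expression and do not measure the deletion. Whether the deletion removes counted sequence of Rorc itself cannot be told. Each hashtag was read as 1 animal, which gives 4 animals per genotype, and hashtags are numbered 2 to 5 in both. Each genotype was a single capture, so a difference between captures and a difference between genotypes cannot be told apart anywhere in these data, and p-values measure the spread between animals within a capture. The mixing ratio of the sort gates is not given in the sources used here.

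The authors' deposited matrices hold UMI counts per gene and per hashtag antibody, made with Cell Ranger 8.0.1 on mm10 per the submitters' processing notes. Per the file headers, the deposited assignment tables hold, for each called cell, a probability for each hashtag as a fraction from 0 to 1, and the hashtag assigned; single-hashtag cells all had an assignment probability of at least 0.9. The annotation behind the gene names and the settings of the hashtag assignment are not given in the sources used here. The labels name the same antibody for hashtags 3 and 4, while the matrices hold 4 separate hashtag antibodies, and the matrices were followed. Of the 32285 gene identifiers, 32158 were found in GENCODE M21 (GRCm38), which supplied coordinates and transcript sequences. It was not used for counting.

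Cells with a single hashtag were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. The mitochondrial limit removed 27.8% of single-hashtag WT cells and 20.2% of KO cells. Doublets within an animal carry a single hashtag, so cells with at least 12 hashtag multiplets among their 50 nearest neighbours were removed as likely doublets, 848 of 13389 WT cells and 1864 of 20363 KO cells. The search took its threshold from the number of within-animal doublets that the multiplets predict, 933 in WT and 1881 in KO. This left 12541 WT and 18499 KO cells. They were clustered with scanpy 1.11.5 on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2), and clusters were named X-like from marker genes fixed beforehand. Rorc, Itgb8, mitochondrial, ribosomal, haemoglobin and sex-linked genes did not enter the clustering. Names come from this clustering and not from an annotation by the authors.

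Counts were summed per animal and class. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, its filter on low counts) with Benjamini-Hochberg adjustment over the genes tested in that class, and a gene is called changed at an adjusted p of 0.05 or less. All log2 fold changes are KO minus WT. Library totals per animal ranged from 9696031 to 16365792 UMIs for ILC3-like cells and from 189714 to 773912 UMIs for the smallest group tested, the Prdm16 cluster. Lists of genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Shares of cells and CPM values of single genes were compared with exact two-sided permutation tests over the 70 assignments of 8 animals to genotypes, whose smallest p is 0.0286. Shares of cells with a Rorc UMI were computed after thinning each cell to 2000 UMIs. Comparisons of the Rorc change between classes used the per-animal difference of log2(CPM + 1).

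The design, the tests, 19 gene lists, the marker genes, the rule for naming genes and a set of alternative settings were fixed before the data were examined. The rule named Rorc, up to 8 raised and 8 lowered genes per class with the largest fold change among changed genes whose animals did not overlap between genotypes and whose mean was at least 20 CPM in the higher genotype, and up to 4 members per gene list with the smallest p. It left out unnamed gene models, mitochondrial, ribosomal, immunoglobulin, T cell receptor, haemoglobin and sex-linked genes. A gene named outside this rule is said to be so. These settings were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a replicate block, 30 cells as a minimum per animal, stricter cell filters, no doublet removal, resolutions 0.6 and 1.5, centring within captures, an assignment probability of at least 0.99, thinned cells, a pseudocount of 5 CPM and leaving out each animal in turn. A mitochondrial maximum of 20%, a clustering that left out every gene changed in any class, and tests of the clusters of the RORgt DC-like class apart were added after seeing the data.

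The labels tie hashtags of the same number only by their antibody. In ILC3-like cells the deviations from the genotype means nevertheless correlated between same-numbered animals across genes, at 0.505, 0.223, 0.196 and 0.401 for hashtags 2 to 5, and Xist and Ddx3y put hashtags 2 and 3 as male and 4 and 5 as female in both genotypes, so sex is balanced and tracks the number. Animals of the same sex with another number correlated at -0.0517, 0.191, 0.288 and 0.201 (WT animals 2 to 5), so sex may account for part of this. The numbers were treated as pairs for ILC3-like cells only. The pipeline was tested on simulated counts drawn from the real means and depths with 100 genes changed 2-fold and 100 changed 4-fold. Of the genes changed 2-fold it recovered 87 in ILC3-like, 82 in RORgt DC-like, 66 in CCR7+ mature DC-like, 86 in cDC1-like and 77 in cDC2-like cells, 56 in the Prdm16 cluster and 78 in the Nrxn1 cluster, none in the wrong direction, and false calls made up 2.86% to 8.77% of calls. The simulated animals were independent, without an effect of capture, sex or hashtag number. These values therefore do not measure recovery or false calls among the real calls.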

Results

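Single-cell RNA was measured in dendritic cells (DCs) and ILC3 from mesenteric lymph nodes of 15-day-old WT mice and mice without the +7kb enhancer of Rorc (KO), with 4 animals per genotype. The WT capture held 24555 called cells, of which 18761 carried a single hashtag, and the KO capture 35966, of which 25857 did. After filtering, 12541 WT and 18499 KO cells were kept. The WT animals kept 3660, 2401, 2888 and 3592 cells, with 34989173, 20912748, 26414888 and 31141189 UMIs (hashtags 2 to 5). The KO animals kept 4407, 4624, 4345 and 5123 cells, with 35699906, 35490842, 33516413 and 44396240 UMIs. Median UMIs per cell lay between 7775 and 8463 in WT animals and between 6719.5 and 7308 in KO animals. Genotype and capture cannot be told apart in any comparison that follows.

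Clustering gave 5 classes for comparison. ILC3-like cells numbered 6546 in WT and 6931 in KO, RORgt DC-like cells 533 and 644, CCR7+ mature DC-like cells 1233 and 3476, cDC1-like cells 1548 and 2437, and cDC2-like cells 2053 and 3511. RORgt DC-like cells are DCs with markers fixed for Rorc-expressing antigen-presenting cells. They formed a cluster led by Nrxn1 (352 WT and 550 KO cells) and a cluster led by Prdm16 (181 and 94 cells). The Nrxn1 cluster made up 66.0% of the class in WT and 85.4% in KO, so values of the whole class mix a change in makeup with changes within cells. In ILC3-like cells cluster 2 was the largest in WT (34.7%) and cluster 1 in KO (36.3%), and in cDC1-like cells cluster 5 was the largest in WT (58.5%) and cluster 6 in KO (50.4%).

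The first comparison asked how far loss of the enhancer lowers Rorc (ENSMUSG00000028150; GRCm38 chromosome 3, 94372794 to 94398276) in each cell class. In ILC3-like cells Rorc fell from 286.3 ± 13.1 to 163.0 ± 10.2 CPM (SD, n = 4 per genotype; exact two-sided permutation p = 0.0286, adjusted 0.0334 over 7 cell groups), a log2 fold change of -0.81 (SE 0.05, adjusted p 1.89e-10). In the Prdm16 cluster it fell from 570.4 ± 54.0 to 207.6 ± 30.5 CPM, a log2 fold change of -1.47 (SE 0.18, adjusted p 2.03e-05). In RORgt DC-like cells as a class it fell from 225.2 ± 24.8 to 65.6 ± 6.47 CPM, a log2 fold change of -1.78 (SE 0.11, adjusted p 1.35e-10). In these 3 groups each of the 4 KO animals lay below each of the 4 WT animals. In the Nrxn1 cluster Rorc was 46.0 ± 9.77 CPM in WT and 34.7 ± 2.43 CPM in KO. There the animals did not overlap (exact p = 0.0286), but edgeR did not call the change (log2 fold change -0.40, SE 0.18, adjusted p 0.363). The value depended on how cells were grouped. It was -0.09 (adjusted p 0.944) with a mitochondrial limit of 20%, -0.28 (0.644) at resolution 1.5, -0.42 (0.414) with the stricter cell filter and -0.67 (0.0993) without doublet removal. At resolution 0.6 it was -1.11 (SE 0.14) and called (adjusted p 6.44e-05). There the cluster also took in 197 WT and 440 KO cells of cluster 13 and 190 and 252 cells of cluster 17, to reach 742 and 1246 cells.

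**Figure D1:**
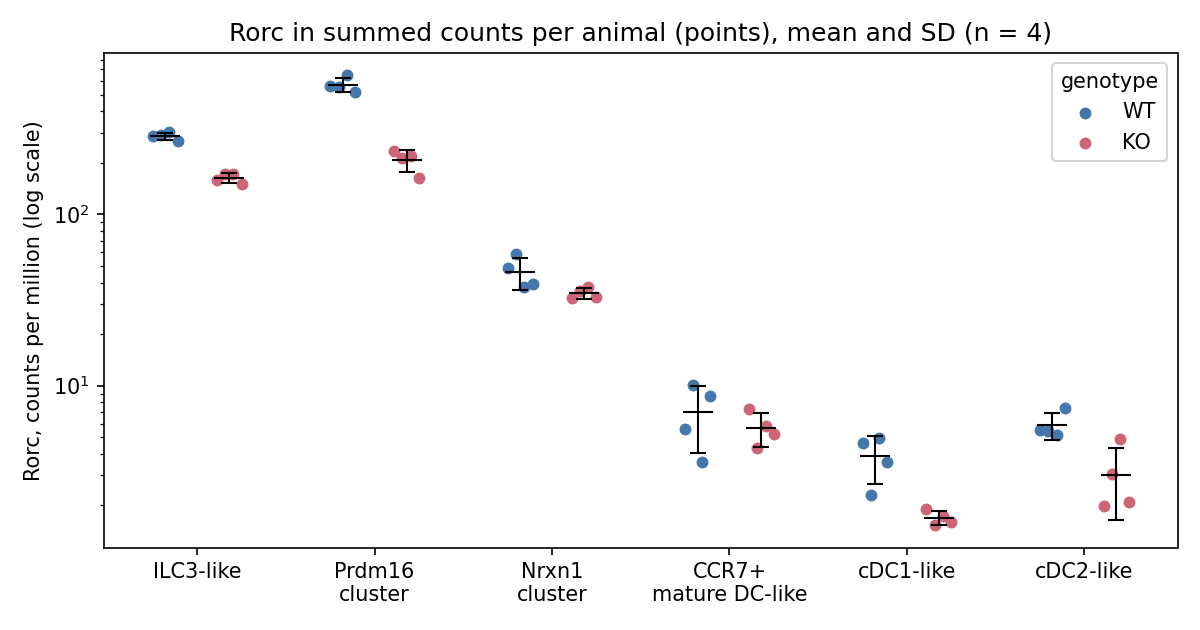
Rorc in CPM (log axis) per animal in 6 cell groups, with the mean and SD of 4 WT and 4 KO animals. KO animals lie below WT animals in ILC3-like cells and the Prdm16 cluster, and levels in cDC1-like and cDC2-like cells are below 8 CPM.

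After each cell was thinned to 2000 UMIs, the share of ILC3-like cells with a Rorc UMI fell from 42.9% ± 1.32 to 25.7% ± 2.53 (SD, n = 4; exact two-sided permutation p = 0.0286). Thinning left out 72 WT and 373 KO cells, and the unthinned shares were 81.2% and 55.0%. In the Prdm16 cluster the thinned share fell from 63.0% ± 6.14 to 31.2%, with KO animals between 15.4% and 44.0% (exact p = 0.0286; 1 WT and 0 KO cells left out), and the unthinned shares were 88.3% and 74.1% (exact p = 0.0571). In the Nrxn1 cluster the thinned shares were 8.21% and 6.99% (exact p = 0.486; 2 and 25 cells left out) and the unthinned ones 27.5% and 19.4% (exact p = 0.0286, KO animals below WT animals). Thinned to 1000 UMIs, with 0 cells left out, the share in the Nrxn1 cluster fell from 5.71% to 3.61% (exact p = 0.0286). That in the Prdm16 cluster went from 42.3% to 17.2% with animals that overlapped (exact p = 0.0571). As a background, cDC1-like cells, which should lack Rorc, gave thinned shares of 1.82% in WT and 0.533% in KO (10 and 29 cells left out), and unthinned ones of 4.71% and 1.97%. Median UMIs were 9866 and 11824 in cDC1-like cells, 8293.5 and 6400 in ILC3-like cells, 9979 and 10125.5 in the Prdm16 cluster, and 10441.5 and 7704 in the Nrxn1 cluster. CCR7+ mature DC-like cells (1.57% and 1.17%; 42 and 189 left out; unthinned 4.65% and 3.93%; median UMIs 7807 and 7141.5) and cDC2-like cells (1.42% and 0.614%; 27 and 103 left out; unthinned 4.64% and 1.94%; median UMIs 6455 and 7181) gave thinned shares below the cDC1-like one in WT and above it in KO.

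Rorc was also lower in KO in cDC1-like cells (3.87 to 1.70 CPM; log2 fold change -1.18, SE 0.29, adjusted p 0.00471; lower in 4 of 4 KO animals) and cDC2-like cells (5.86 to 3.00 CPM; -0.97, SE 0.29, adjusted p 0.0267; lower in 4 of 4). The call in cDC2-like cells was lost without WT animal 2 (-1.02), WT animal 5 (-0.84), KO animal 2 (-0.84) or KO animal 5 (-0.83). In near-empty droplets Rorc reached 126.0 CPM in WT and 56.5 CPM in KO. Rorc in cDC1-like cells was 3.07% of that level in WT and 3.00% in KO. For 9 ILC3 marker genes the median percentage was 2.58% in WT and 2.85% in KO, so Rorc in cDC1-like cells lay at the level of free RNA. In CCR7+ mature DC-like cells Rorc was 6.99 ± 2.95 CPM in WT and 5.67 ± 1.27 CPM in KO (-0.25, SE 0.28, adjusted p 0.700). KO animals held 4.33 to 7.34 CPM there and 1.98 to 4.90 CPM in cDC2-like cells, above the 1.55 to 1.91 CPM of cDC1-like cells. The level of free RNA is not shown to account for Rorc in these 2 classes.

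The size of the Rorc change was then compared between classes, on the scale of log2(CPM + 1) and against ILC3-like cells of the same animals. Rorc fell further in RORgt DC-like cells by a difference of -0.95 (exact two-sided permutation p = 0.0286, adjusted 0.0381 over 4 differences; all KO animals below all WT animals). The difference was -0.65 for the Prdm16 cluster (exact p = 0.0286, adjusted 0.0381) and 0.43 for the Nrxn1 cluster (exact p = 0.0286, adjusted 0.0381, KO animals above WT animals). Over 6 other ways to filter, thin or cluster cells the difference stayed between -1.04 and -0.87 for the class and between -0.82 and -0.58 for the Prdm16 cluster (exact p = 0.0286 in each). For the Nrxn1 cluster, where Rorc in thinned cells was too low to test, it did not hold in all of the other 5. It was 0.72 at 20% mitochondrial UMIs and 0.54 at resolution 1.5 (exact p = 0.0286 for each). The animals overlapped with the stricter cell filter (0.40, exact p = 0.0857), without doublet removal (0.23, exact p = 0.314) and at resolution 0.6, where the sign turned (-0.27, exact p = 0.2). For CCR7+ mature DC-like cells it was 0.61 (exact p = 0.143), and with a pseudocount of 5 it was 0.65 (exact p = 0.0286). The value for the whole RORgt DC-like class includes its smaller share of Prdm16 cluster cells in KO, which held more Rorc than Nrxn1 cluster cells.

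The next comparison asked whether cell shares differ. All p are exact two-sided permutation values with 4 animals per genotype, for which 0.0286 is the smallest they can give. ILC3-like cells fell from 52.7% ± 8.71 to 37.5% ± 3.16 of kept cells, a difference of -15.2 points (exact p = 0.0286, adjusted 0.0477 over 5 classes). Clustered without the genes called changed in any class, the difference was -14.9 points (exact p = 0.0571). The call for the share of ILC3-like cells was lost on leaving out KO animal 2 (-14.3), KO animal 3 (-16.6), KO animal 4 (-15.3) or KO animal 5 (-14.5; exact p = 0.0571 each). Because DCs and ILC3 were sorted through separate gates, the mixture of the gates can set this share.

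Among cells of the DC classes, RORgt DC-like cells fell from 10.2% ± 1.27 to 6.43% ± 1.18, by -3.79 points (exact p = 0.0286, adjusted 0.0477), and by -2.57 points when clustered without changed genes (exact p = 0.0857). The Prdm16 cluster fell from 3.55% ± 0.868 to 0.937% ± 0.130 of these cells, by -2.61 points, with each KO animal below each WT animal (exact p = 0.0286; adjusted over 8 further cell groups 0.229). Clustered without changed genes it fell by -2.24 points (exact p = 0.0286). The Nrxn1 cluster went from 6.67% ± 0.439 to 5.49% ± 1.05 (exact p = 0.0857), without changed genes from 8.39% to 8.06% (exact p = 0.714). With the stricter cell filter it fell from 7.47% to 5.13% (exact p = 0.0286, KO animals below WT animals). Per 100 ILC3-like cells the Prdm16 cluster counted 2.88 ± 0.906 cells in WT and 1.36 ± 0.0705 in KO, and per 100 cDC1-like and cDC2-like cells 5.27 ± 1.33 and 1.58 ± 0.140 (exact p = 0.0286 for each).

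**Figure D2:**
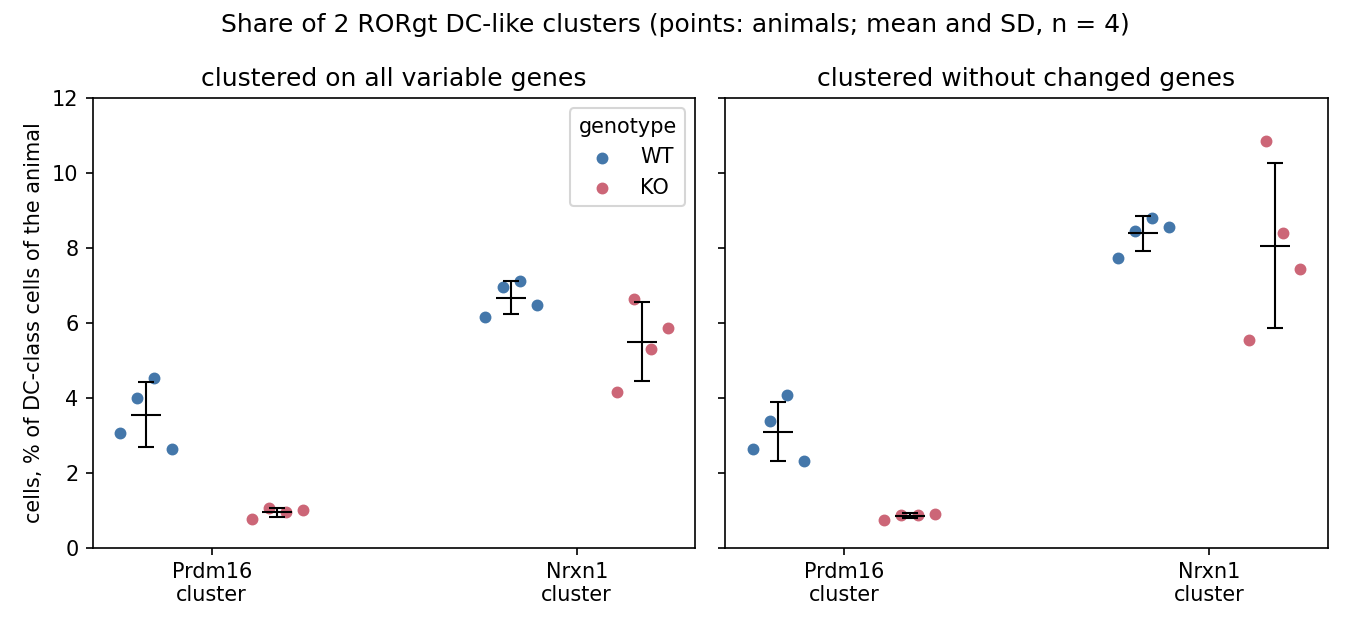
Cells of the Prdm16 and Nrxn1 clusters as a percentage of DC-class cells per animal, clustered on all variable genes (left) and without changed genes (right), with the mean and SD of 4 animals per genotype. KO animals lie below all WT animals for the Prdm16 cluster in both panels, and overlap with them for the Nrxn1 cluster.

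The share of cDC1-like cells fell from 28.8% ± 1.84 to 24.3% ± 2.15 of DC-class cells (-4.58 points; exact p = 0.0286, adjusted 0.0477), a call lost without WT animal 3 (-3.75) or KO animal 5 (-3.55). Calls under other settings are given by the exact p before adjustment. Adjusted over 5 classes, the share of RORgt DC-like cells also missed 0.05 with genes centred within captures (-3.90 points, adjusted p 0.0714) and with the stricter cell filter (-5.12 points, 0.0715). So did the share of ILC3-like cells with that filter (-21.0 points, 0.0715). The share of cDC1-like cells missed it at resolution 0.6 (-4.03 points, 0.0952), with centring (-4.47 points, 0.0714) and without changed genes (-3.92 points, 0.0952). CCR7+ mature DC-like cells went from 22.3% ± 4.196 to 34.2% ± 7.38 (11.99 points; exact p = 0.0571, adjusted 0.0714), and by 14.6 points without KO animal 3 (exact p = 0.0286). The DC classes have a common total, so a larger share of these cells lowers the shares of the others. Falls in the shares of cDC1-like cells, RORgt DC-like cells and the Nrxn1 cluster were not tested apart from this. cDC2-like cells went from 38.7% ± 4.84 to 35.1% ± 5.56 (exact p = 0.343). Of kept cells, T cell-like cells made up 0.389% in WT and 2.61% in KO (exact p = 0.914), NK or ILC1-like cells 1.13% and 1.01% (exact p = 0.543), and B cell-like cells 0.306% and 0.250% (exact p = 0.571). These small shares depend on the settings: with genes centred within captures NK or ILC1-like cells fell from 0.517% to 0.171%, and at 20% mitochondrial UMIs B cell-like cells fell from 0.577% to 0.188% (exact p = 0.0286 for each, unadjusted, KO animals below WT animals). KO animal 5 held 9.45% T cell-like cells and the other KO animals 0.276% to 0.408%.

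Expression was compared in each class on counts summed per animal. In ILC3-like cells 3834 of 13607 genes tested were called changed, 1926 higher and 1908 lower in KO, of which 359 changed at least 2-fold. In RORgt DC-like cells 943 of 10046 were called (398 higher, 545 lower), in cDC1-like cells 2675 of 11699 (1751 and 924) and in cDC2-like cells 2107 of 12211 (1241 and 866). CCR7+ mature DC-like cells had 162 of 11355 (67 and 95), the Prdm16 cluster 201 of 5860 (111 and 90) and the Nrxn1 cluster 113 of 9124 (54 and 59). The animals of the genotypes did not overlap for 3246 of the ILC3-like calls, and among all genes tested in ILC3-like cells this held for 28.4%, against 2.86% by chance. Of the 943 calls in RORgt DC-like cells, 209 were also called in the Prdm16 or the Nrxn1 cluster and 734 in neither. The number in CCR7+ mature DC-like cells rested on single animals: it was 742 without WT animal 2, 85 without WT animal 3, 76 without WT animal 4, 59 without WT animal 5, 79 without KO animal 2, 358 without KO animal 3 and 61 without KO animal 4. In the Prdm16 cluster it was 125 without WT animal 2, 105 without WT animal 4 and 104 without KO animal 5, and in the Nrxn1 cluster 74 without WT animal 2, 178 without WT animal 4, 59 without WT animal 5, 63 without KO animal 2 and 54 without KO animal 4.

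**Figure D3:**
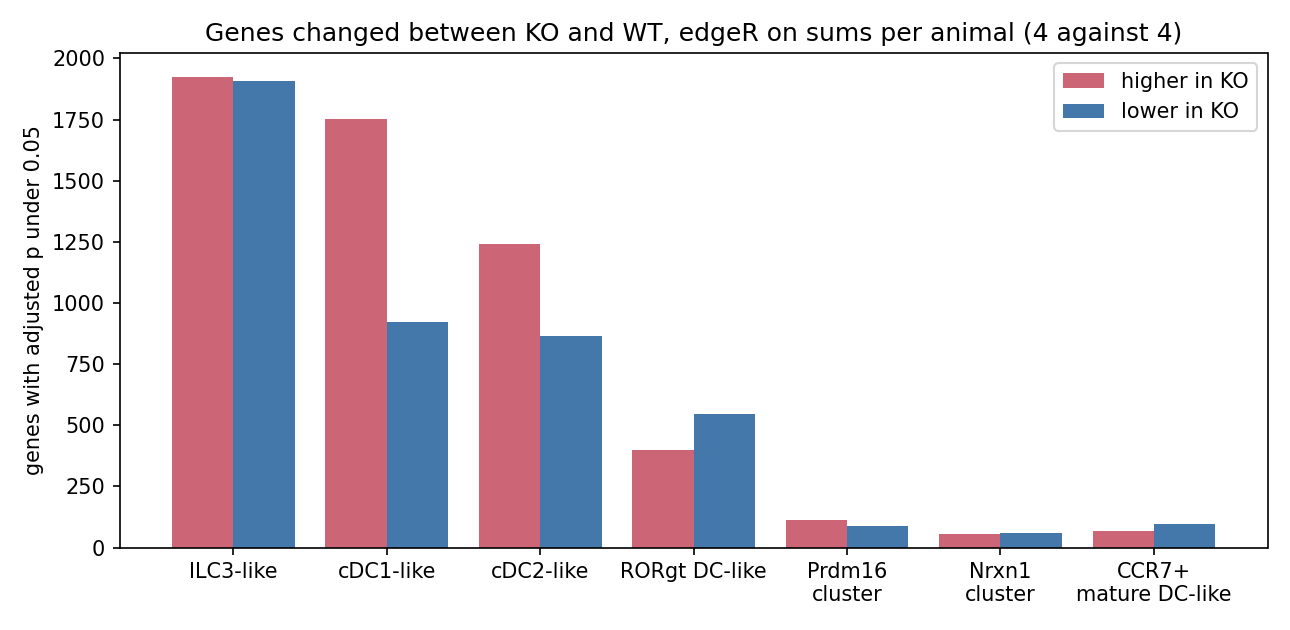
Number of genes called changed between 4 KO and 4 WT animals in each cell group (edgeR, adjusted p under 0.05), split into higher and lower in KO. ILC3-like cells had 1926 higher and 1908 lower, and CCR7+ mature DC-like cells 67 and 95.

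In ILC3-like cells the named raised genes were led by Ms4a4b (log2 fold change 1.73, SE 0.17, adjusted p 4.80e-04; 45.0 to 149 CPM), followed by Ddit4 (1.43), Cd244a (1.43), Wdr89 (1.39), Xdh (1.38), AW112010 (1.34) and Ctla4 (1.28). The named lowered genes were led by Myof (-2.84, SE 0.11, adjusted p 4.07e-13; 28.7 to 4.02 CPM), followed by Polr2l (-1.81), Pde7b (-1.71), Cacnb2 (-1.54), Dpp10 (-1.53) and Dscaml1 (-1.32). All of these separated the 4 KO from the 4 WT animals, which the rule for naming genes required. Ftl1-ps1 (1.36) and Gstp1 (-2.72) share most of their transcript end with another gene and are uncertain. Ccr6, a gene of the sort, fell by 0.43 on the log2 scale (SE 0.04, adjusted p 2.04e-07). Lingo4 (ENSMUSG00000044505), which starts 241 bp after the end of Rorc, was chosen after its values were seen and fell from 71.5 to 31.4 CPM (log2 fold change -1.18, SE 0.05, adjusted p 7.50e-12). The antisense gene Gm43401 overlaps both Rorc and Lingo4, and reads of overlapping genes may have been split between them.

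In the Prdm16 cluster, among named genes, Ddr1 rose from 27.5 to 194 CPM (log2 fold change 2.82, SE 0.25, adjusted p 2.33e-07), Mdh2 from 187 to 779 CPM (2.06, SE 0.21) and Srgap3 from 222 to 853 CPM (1.93, SE 0.26), and Klri1 (2.66, with 33.6% of its transcript end in another gene), Alox5ap (2.37) and Apol10b (1.96) also rose. Stab2 fell from 208 to 14.04 CPM (-3.89, SE 0.35, adjusted p 2.33e-07), and Cd69 (-3.46), Cldn7 (-3.27), Dpysl3 (-3.14), Adra1a (-2.62) and Tfap2a (-2.57) fell too. Aif1l had 0 UMIs in the 94 KO cells of this cluster and 59.7 CPM in WT, which is at least 21.8-fold lower against a floor of 3 counts over the group. Tmem132c (2.97), Ryr3 (2.33) and Prkg1 (-6.44) also changed there, but they lead clusters 13 and 17, which carry no class name. In each of these genes the 4 KO animals lay apart from the 4 WT animals, as the rule for naming genes required.

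In RORgt DC-like cells as a class, Ppp1r14a (1.74), Ifitm3 (1.54), Klri1 (1.54), Ddah1 (1.46) and Wdr89 (1.34) were among the named raised genes, and Aif1l (-5.16), Gpr39 (-4.71), Stab2 (-4.53), Cldn7 (-4.06), Fabp1 (-2.87) and L3mbtl1 (-2.80) among the lowered ones. In the Nrxn1 cluster Ddah1 (1.32), Nfia (1.30), Ifitm3 (1.27) and Ppp1r14a (1.23) rose, and Polr2l (-1.75), Kif26b (-1.62) and Dhcr7 (-1.23) fell; Gstp1 (-3.99) and Ftl1-ps1 (1.51) are uncertain for the copies named above. Ifitm3 (33.0%) and Klri1 (33.6%) share a smaller part of their transcript end with another gene, as do Wdr89 (36.0%) and Polr2l (24.4%), and copies are not excluded for these 4. Itgb8 (ENSMUSG00000025321; GRCm38 chromosome 12, 119158022 to 119238802), which encodes an integrin that activates TGF-beta, went from 36.2 ± 8.97 to 20.5 ± 8.45 CPM in RORgt DC-like cells (n = 4; log2 fold change -0.87, SE 0.24, adjusted p 0.0213), with animals that overlapped. The call was lost without WT animal 4 (-0.79), WT animal 5 (-0.75), KO animal 3 (-0.78), KO animal 4 (-0.81) or KO animal 5 (-0.74). Itgb8 was not called within the Prdm16 cluster (-0.78, SE 0.31, adjusted p 0.182) or the Nrxn1 cluster (0.13, adjusted p 0.935).

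In cDC1-like cells Ifitm3 (1.64), Wdr89 (1.62), Anks1b (1.58), Ddah1 (1.46), Map7 (1.31) and Plac8 (1.30) rose, and Polr2l (-1.55), Hes1 (-1.41), Lars2 (-1.33) and Gphn (-1.12) fell. In cDC2-like cells Ddah1 (1.81), Wdr89 (1.63), Ctla4 (1.62), Gria3 (1.33) and AW112010 (1.26) rose, and Plk3 (-1.61), Polr2l (-1.49), Nr4a3 (-1.36), Zfand2a (-1.33) and Klhl11 (-1.33) fell. In CCR7+ mature DC-like cells Grik3 (1.76), Wdr89 (1.30) and Plac8 (0.98) rose, and Larp4 (-1.74), Polr2l (-1.71), Rasgef1b (-1.40) and Tent5c (-1.08) fell. The KO and WT animals did not overlap in any of these genes, a condition of the rule for naming genes. Hist1h2ap fell in cDC1-like (-3.96) and cDC2-like cells (-3.38), but 93.4% of its transcript end is found in another gene, and Hist1h4h, Hist1h4m, Hist2h2aa1 and Hmga1 are uncertain for the same reason.

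Calls were shared between classes: 53 of the 9188 genes tested in all 5 classes changed in the same direction in each, 32 higher and 21 lower in KO, and 0 changed in mixed directions. If calls were independent, 0.0083 higher and 0.0033 lower genes would be expected, but the classes come from the same 8 animals and 2 captures and are not independent. Wdr89, Ctla4, Ddah1 and Ftl1-ps1 were among the higher genes and Polr2l among the lower ones. However, 36.0% of the transcript end of Wdr89 and 24.4% of that of Polr2l are found in another gene. cDC1-like and cDC2-like cells shared 1343 calls of the same direction, against 251 expected from independent lists, and 1467 of the 3834 calls in ILC3-like cells had the same direction in cDC1-like or cDC2-like cells, where Rorc was below 8 CPM.

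Gene lists were tested in each class. With the preset correlation 9 of 19 lists passed in ILC3-like, 6 of 17 in RORgt DC-like, 6 of 18 in CCR7+ mature DC-like, 7 of 19 in cDC1-like and 9 of 18 in cDC2-like cells, 5 of 17 in the Prdm16 cluster and 9 of 17 in the Nrxn1 cluster. With an estimated correlation only the circadian clock list and the list of RORgt and type 3 genes in RORgt DC-like cells held (adjusted p 0.0106 for each), and 0 lists held in any other group. Both lost these calls with the hashtag number, which sex tracks, as a block. The clock list in RORgt DC-like cells had 6 of 12 tested genes lower and 0 higher (8 and 0 adjusted over the list alone; median log2 fold change -0.51, adjusted p 3.05e-08). The list of RORgt and type 3 genes had 6 of 13 lower and 0 higher, and 7 and 0 adjusted over the list alone (median -0.40, adjusted p 3.83e-07), with Ahr (-1.03), Il1r1 (-0.57) and Kit (-0.40) besides Rorc. It also passed with the preset correlation in cDC1-like cells (6 of 15 lower and 0 higher, median -0.37, adjusted p 0.00114), where Rorc lay at the level of free RNA. So it did in cDC2-like cells (3 of 16 lower, median -0.15, adjusted p 0.0184), the Prdm16 cluster (2 of 11 lower and 1 higher, adjusted p 0.0294) and the Nrxn1 cluster (0 of 11, adjusted p 0.00178). In cDC1-like cells Il1r1 of this list (3.43 CPM in WT, 1.65 CPM in KO) was 2.83% and 2.14% of its level in near-empty droplets. That level itself fell from 121.1 to 77.2 CPM. Kit lay far above such percentages (79.9% in WT and 99.9% in KO). Free RNA may thus lower part of the list in cDC1-like cells. Whether the list falls in cells without Rorc cannot be told from these passes. That list did not pass in ILC3-like cells, where its median was 0.03, its mean -0.09 and its test pointed down (adjusted p 0.723).

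In ILC3-like cells the lists below passed with the preset correlation and not with an estimated one. The clock list had 10 of 16 genes lower and 0 higher, and 10 and 0 adjusted over the list alone (median -0.30, adjusted p 4.21e-05, estimated 0.203), with Npas2 (-0.90), Nr1d1 (-0.67) and Nr1d2 (-0.28) among them. MHC class I genes had 10 of 20 higher and 0 lower, and 12 and 0 adjusted over the list alone (median 0.43, adjusted p 1.93e-07, estimated 0.448); with the hashtag number as a block 19 were higher. Interferon genes had 4 of 32 higher and 0 lower, and 2 and 0 adjusted over the list alone (median 0.60, adjusted p 3.79e-04, estimated 0.625), and 17 higher with the block. Immediate early and heat shock genes had 12 of 30 lower and 0 higher, and 16 and 0 adjusted over the list alone (median -0.53, adjusted p 1.61e-06, estimated 0.448), and 21 lower and 1 higher with the block. The mean log2 level per animal overlapped between genotypes for the interferon list (difference 0.55, exact two-sided permutation p = 0.171), with KO animals 2 and 4 and WT animal 2 above the other 5. It also overlapped for MHC class I (0.46, exact p = 0.0571) and for immediate early and heat shock genes (-0.46, exact p = 0.0571). For the clock list it did not overlap (-0.32, exact p = 0.0286). Between animals of the same hashtag number, which these tests do not use, the KO animal lay above the WT animal in 4 of 4 pairs for interferon and MHC class I and below it in 4 of 4 for the other 2 lists. An exact sign-flip test of 4 pairs can give no p below 0.125, and gave that for each. The test pointed up for migratory DC maturation (14 of 22 higher, 4 lower; 16 and 4 adjusted over the list alone), the cell cycle (13 of 37 and 2; 13 and 2) and MHC class II (8 of 17 and 1; 8 and 1). It pointed down for glycolysis (1 of 18 and 8; 1 and 9) and cholesterol synthesis (0 of 24 and 6; 0 and 5).

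Immediate early and heat shock genes passed with the preset correlation in all 7 cell groups, each time pointing down, and in 0 of them with an estimated one. Besides ILC3-like cells, lower and higher genes numbered 11 and 0 of 28 in RORgt DC-like (median -0.55), 7 and 0 of 28 in CCR7+ mature DC-like (-0.56), 3 and 1 of 30 in cDC1-like (-0.50) and 10 and 1 of 30 in cDC2-like cells (-0.53), 3 and 0 of 26 in the Prdm16 cluster (-0.22) and 2 and 0 of 26 in the Nrxn1 cluster (-0.53). Adjusted over the list alone they numbered 13 and 0, 14 and 0, 1 and 1, 12 and 1, 4 and 0, and 12 and 0 in that order. The mean level per animal was lower in each KO animal than in each WT animal in RORgt DC-like cells (-0.68, exact two-sided permutation p = 0.0286). It overlapped in CCR7+ mature DC-like (-0.53, exact p = 0.0571), cDC1-like (-0.50, exact p = 0.0857) and cDC2-like cells (-0.60, exact p = 0.0571).

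In cDC2-like cells the clock list had 3 of 13 genes lower and 0 higher, and 6 and 0 adjusted over the list alone (median -0.42, adjusted p 6.49e-04, estimated 0.319), with Cry1 (-0.71), Per3 (-1.14) and Cry2 (-0.54) among them. In the Prdm16 cluster Npas2 fell by 1.23 on the log2 scale (SE 0.25, adjusted p 0.00552) and Nr1d1 was not called (-1.21, SE 0.34, adjusted p 0.0506). Lists of co-stimulation, genes flanking Rorc, haemoglobin, effector molecules of lymphoid tissue inducer cells, RORgt DC and Aire genes, sex-linked genes and Treg induction passed in 0 of the cell groups. With the preset correlation the list of NF-kB and inflammatory genes passed in CCR7+ mature DC-like cells only, and the TGF-beta list in RORgt DC-like, cDC1-like and cDC2-like cells and the Nrxn1 cluster. With an estimated one neither passed in any group. Among lists that did not pass, median, mean and test also differed in sign for RORgt DC and Aire genes in ILC3-like and cDC2-like cells, MHC class II in RORgt DC-like and CCR7+ mature DC-like cells and the Nrxn1 cluster, sex-linked genes in RORgt DC-like and cDC2-like cells, Treg induction in RORgt DC-like and CCR7+ mature DC-like cells and the Nrxn1 cluster, co-stimulation and effector molecules in cDC1-like cells, and MHC class I in the Prdm16 cluster.

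**Figure D4:**
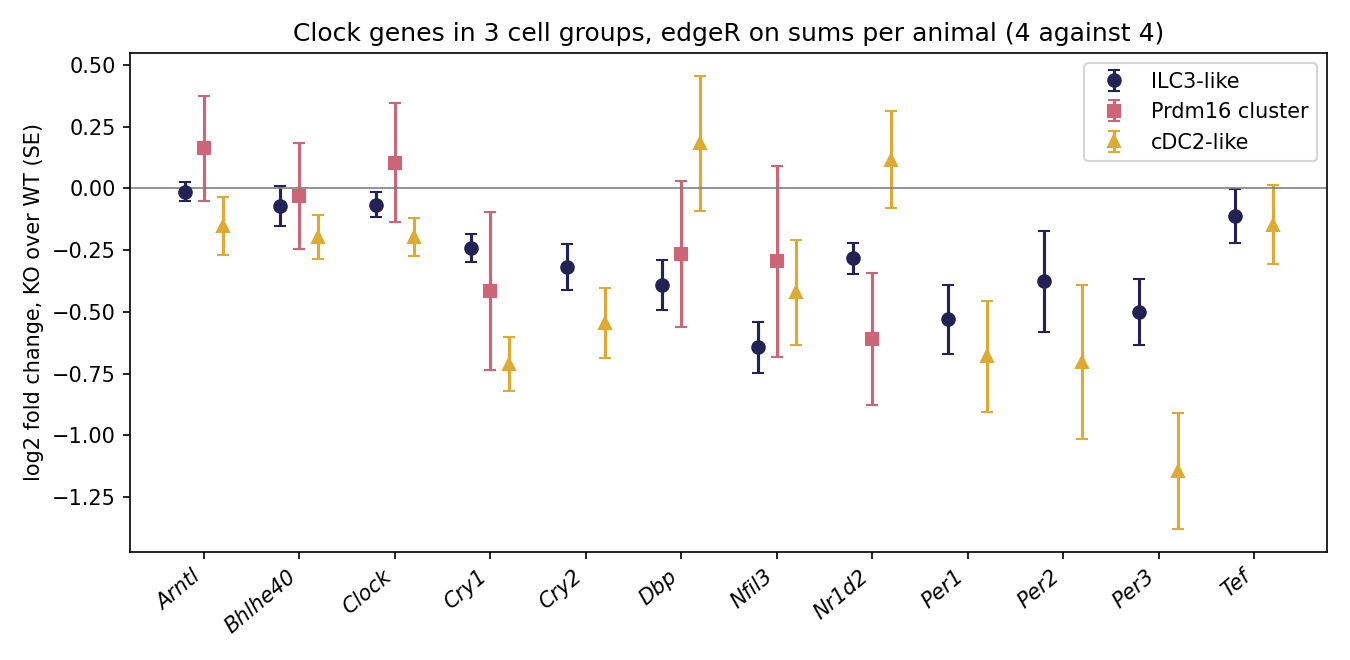
Log2 fold changes (KO over WT) with their SE of the 12 genes of the clock list tested in both ILC3-like and cDC2-like cells, from 4 animals per genotype, with the Prdm16 cluster where tested. All lie below 0 in ILC3-like cells, and all but Dbp and Nr1d2 in cDC2-like cells.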

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

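The tests of free RNA, of the clock genes, of the Prdm16 cluster and of the splits of the samples were chosen only after the result was seen; those of near-identical copies and of linked loci were not. In all comparisons genotype and capture cannot be told apart, so a difference between captures stays open for each pattern.

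T cell-like cells made up 9.45% of the kept cells of KO animal 5 and 0.276% to 0.408% of those of the other KO animals, a sample far from its group. Rorc in cDC2-like cells of WT animal 5 was 7.39 CPM against 5.17 to 5.48 CPM in the other WT animals, also far from its group. Of 48 groups of 4 animals examined these 2 stood out, where chance picks about 1 in 20 groups, or 2.4 here. The Rorc change differed from that in ILC3-like cells by -0.95 in RORgt DC-like cells, -0.65 in the Prdm16 cluster and 0.43 in the Nrxn1 cluster, differences between cell groups that an exact test picked out. The one in the Nrxn1 cluster turned sign at resolution 0.6 (-0.27, exact two-sided permutation p = 0.2) and is not relied on. Cluster 17, which belongs to no compared class, had a Rorc UMI in 48.7% of its WT and 26.6% of its KO cells, a signal outside the compared classes, against 4.71% and 1.97% in cDC1-like cells, all unthinned, with median UMIs of 11886 and 10202 in the cluster and 9866 and 11824 in cDC1-like cells. Not every group outside the compared classes showed a fall. NK or ILC1-like cells had a Rorc UMI in 39.65% of WT and 41.81% of KO cells (unthinned, exact two-sided permutation p = 0.743). Thinned to 2000 UMIs, their shares were 22.57% and 21.04% (exact p = 0.743). T cell-like cells, 48 in WT and 528 in KO, had 25.43% and 29.98% (unthinned, exact p = 0.686). Near-empty droplets held 77 Rorc UMIs in WT and 41 in KO, a signal in droplets that no comparison uses.

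The 53 genes that changed in the same direction in all 5 classes were weighed first, since Rorc in cDC1-like and cDC2-like cells was below 8 CPM. Free RNA that differed between captures would have to supply most of their change, and it supplied a median of 2.12% of it in cDC1-like cells, which argues against it. DNA of another strain kept around the edited locus would gather these genes in a region. A window of 10 Mb held at most 3 of them, while 1000 random draws had a median of 3. The window could lie anywhere in the genome, so a few genes near Rorc would not stand out and are not excluded. Hist2h2aa1 starts at 96245497 on chromosome 3, which also holds Rorc, but 100% of its transcript end is found in another gene. For 15 of them (28.3%, against 3.2% of 1000 other genes) most of the transcript end is found in another gene, so reads shared with copies cannot be told apart from a real change there. Of the other 38, Wdr89 (36.0%), Polr2l (24.4%), AC154200.1 (23.1%) and Lsm5 (22.5%) share a smaller part, and copies stay open for these too. The enhancer deletion acting through other cells of the animal and a difference between the captures both stay open, untested.

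The clock genes were weighed next, over the 12 genes of the list tested in both ILC3-like and cDC2-like cells. Captures collected at a different hour may explain them, since an hour would act on both classes: the mean log2 level of these genes changed by -0.27 in ILC3-like and by -0.336 in cDC2-like cells, each KO animal below each WT animal (exact two-sided permutation p = 0.0286 for each). Lower Rorc in the cells that express it would lower them further in ILC3-like cells. The change in cDC2-like cells minus that in ILC3-like cells was -0.0618 (exact p = 0.371), which shows no larger fall in ILC3-like cells. In RORgt DC-like cells, where Rorc fell further, the list fell more than in cDC1-like cells (by -0.31, exact p = 0.0286) but against cDC2-like cells the animals overlapped (-0.256, exact p = 0.0571), over 10 genes each. Npas2 and Nr1d1, not tested in cDC1-like and cDC2-like cells, are not among them. Within the clusters of that class, which its makeup does not affect, no difference passed over the 7 and 9 genes tested: -0.0728 against cDC2-like and -0.0815 against cDC1-like cells in the Prdm16 cluster (exact p = 0.486 for each), 0.00866 (exact p = 1.0) and -0.0799 (exact p = 0.514) in the Nrxn1 cluster. An effect of Rorc on the clock genes cannot be told apart from the hour or the capture. An hour that acts differently on each cell type was not tested.

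The smaller Prdm16 cluster in KO animals was weighed last. Clustering without the changed genes left a difference of -2.24 points beside -2.61, which argues against cells moved to another cluster by those genes. A mitochondrial limit of 20% gave -2.80 points, which argues against a loss of cells to the limit. Another mixture of the sort gates would leave the ratios to ILC3-like cells or to cDC1-like and cDC2-like cells alike, and both fell (highest exact two-sided permutation p = 0.0286). A smaller cluster may thus reflect the genotype, with the capture left open. Loss of cells at the sort stays open too, untested: Ccr6, a gene of the ILC3 gate, was lower in KO ILC3-like cells.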

How the results depend on the processing

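The tests with a mitochondrial limit of 20%, without changed genes, of the Prdm16 and Nrxn1 clusters apart, and of the difference of the Rorc change with other filters or clusterings were chosen only after the data were seen. The difference of the Rorc change between ILC3-like and RORgt DC-like cells kept direction and side of the threshold in all 16 alternatives run (-0.9996 to -0.92 on leaving out animals, -1.04 to -0.65 over all), and so did Rorc in ILC3-like (-0.84 to -0.78) and RORgt DC-like cells (-1.85 to -1.70). Of 10929 values of 589 named genes, 10035 kept direction and side, 623 lost the call, 268 gained it and 3 reversed. These were Traf1 in RORgt DC-like cells at resolution 0.6 (0.0293), and Il7r in cDC1-like cells (0.0271) and Ltb in cDC1-like cells (0.0363) without doublet removal; the cause was not tested.

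Leaving out each animal in turn, genes changed ranged from 3163 to 3556 in ILC3-like, 648 to 891 in RORgt DC-like, 59 to 742 in CCR7+ mature DC-like, 1875 to 3088 in cDC1-like and 1451 to 2416 in cDC2-like cells. Lists changed ranged from 8 to 9, 5 to 7, 4 to 8, 7 to 8 and 8 to 10 in the same order. The difference in the share of ILC3-like cells ranged from -18.8 to -11.8 points, in the share of RORgt DC-like cells from -4.21 to -3.27, in the share of CCR7+ mature DC-like cells from 8.98 to 14.6, in the share of cDC1-like cells from -5.22 to -3.55 and in the share of cDC2-like cells from -5.24 to -1.01. Rorc ranged from -0.42 to -0.06 in CCR7+ mature DC-like, -1.35 to -1.05 in cDC1-like and -1.30 to -0.83 in cDC2-like cells, and Itgb8 from -1.14 to -0.74.

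With cells thinned to 2000 UMIs, 2055 genes were called in ILC3-like, 384 in RORgt DC-like, 155 in CCR7+ mature DC-like (96 higher and 59 lower, beside 67 and 95), 1368 in cDC1-like and 1391 in cDC2-like cells, 67 in the Prdm16 and 49 in the Nrxn1 cluster, with fewer genes tested. The genes changed in CCR7+ mature DC-like cells were 297 with DESeq2 and 780 without the filter on low counts, where 60.9% were higher beside 41.4%. cDC2-like cells gave 829 with the stricter cell filter, 658 at resolution 1.5 (70.4% higher beside 58.9%) and 971 at 20% mitochondrial UMIs. The Prdm16 cluster gave 331 without the filter, and the Nrxn1 cluster 265 without it, 414 at resolution 0.6 and 71 at 20%. With an estimated correlation 0, 2, 0, 0 and 0 lists passed. The cause was not tested for the other changes.

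By the exact p before adjustment, the ILC3-like share lost its call at resolution 0.6 (-15.0), with genes centred within captures (-14.9), at 20% (-12.5) and without changed genes (-14.9). The RORgt DC-like share lost it at resolution 0.6 (-3.82) and without changed genes (-2.57), and the cDC1-like share with the stricter filter (-4.00) and at 20% (-3.77). The CCR7+ mature DC-like share passed at resolution 1.5 (15.6) and at 20% (16.8). The cDC2-like share passed at resolution 1.5 (-7.63) and at 20% (-10.03), and reversed with the stricter filter (0.0942), with which the Nrxn1 cluster share passed (-2.33). At resolution 1.5 a cluster of 375 WT and 1153 KO cells carried no class name, and at 20% a cluster of 660 and 1556 cells. Adgrl3 and Ctnnd2 were among the leading genes of both, as of the largest cDC2-like cluster in the main clustering. Cells without a class name leave the cDC2-like class and the DC total, so shares at both settings depend on the naming. Rorc reversed in CCR7+ mature DC-like cells with the stricter filter (0.00029), lost its call in cDC1-like cells with it (-0.98) and without doublet removal (-0.50), and in cDC2-like cells with it (-0.74) and at 20% (-1.29). The share of cells with a Rorc UMI lost its call in cDC1-like cells thinned to 1000 UMIs (-0.181), passed in cDC2-like cells thinned to 1000 (-0.609) and unthinned (-2.70), lost its call in the Prdm16 cluster at both (-25.1, -14.2) and passed in the Nrxn1 cluster at both (-2.10, -8.11). Itgb8 lost its call at 20% (-0.65). The cause of the other changes was not tested.

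With the hashtag number as a replicate block, 3848 genes were called in ILC3-like, 1045 in RORgt DC-like, 904 in CCR7+ mature DC-like (54.8% higher), 2555 in cDC1-like and 2053 in cDC2-like cells. Outside ILC3-like cells same-numbered animals did not all correlate above 0.1 (hashtag 3 in cDC1-like cells -0.117), so there the numbers were not read as pairs, although sex tracks them. The block also brought RORgt DC and Aire genes in RORgt DC-like cells (adjusted p 0.0125), genes flanking Rorc in CCR7+ mature DC-like (0.0329) and cDC2-like cells (0.0497), and migratory DC maturation in the Prdm16 (0.0184) and Nrxn1 clusters (0.0205) past the threshold at the preset correlation. With an estimated one 0 lists passed under the block, and the clock and RORgt lists in RORgt DC-like cells lost their calls (0.0951 each, beside 0.0106). Of 591 values of named genes under the block 536 kept their call, 13 lost it and 42 gained it, and the block changed no other call.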

Other observations

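The tests of Lingo4 and of the splits of the samples were chosen only after the result was seen. Lingo4 fell together with Rorc, and transcripts of Rorc that run on into Lingo4 are a candidate explanation. They would keep the ratio of both genes, but in ILC3-like cells the log2 ratio of Lingo4 to Rorc changed by -0.37 (n = 4; exact two-sided permutation p = 0.0286), so Lingo4 fell further than Rorc, which argues against them as the whole cause. An effect of the enhancer on Lingo4 itself stays open, untested.

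The 8 animals can be split into groups of 4 in 35 ways. Only the real split, 1 of 35, gave as many changed genes in ILC3-like cells (3834, highest other 10), RORgt DC-like cells (943, 6), cDC1-like cells (2675, 8), cDC2-like cells (2107, 7), the Prdm16 cluster (201, 8) and the Nrxn1 cluster (113, 7). This does not exclude chance, since 1 of 35 is the smallest share that the splits can give. Every other split also mixes the genotypes on both sides. A difference between genotypes or captures then widens the spread within its groups and lowers its count. In ILC3-like cells, where hashtag numbers were treated as pairs, the highest other of the 8 splits that part all pairs gave 0 genes. In CCR7+ mature DC-like cells 2 of 35 splits gave as many, and chance cannot be excluded: the split of WT animal 2 and KO animals 2, 4 and 5 against the rest gave 726 genes beside 162, which points to a structure of the samples. That split puts both animals of hashtag 2 on one side, whose deviations correlated at 0.535 in these cells. It also parts the animals by the mean log2 level of the interferon list, 4.49 to 5.30 against 3.78 to 4.07. UMI totals of the class part them too, 5655493 or more against 4738731 or fewer. Which of these gives the 726 genes was not tested. With the hashtag number as a block the real split gave 904.

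Cluster 13 (209 WT and 480 KO cells) and cluster 17 (197 and 259 cells) carry no class name and entered no comparison of expression. Cluster 13 made up 1.63% of kept WT and 2.62% of kept KO cells (exact two-sided permutation p = 0.200), and cluster 17 1.56% and 1.41% (exact p = 0.400). The ILC3-like cluster led by interferon genes held 6.59% ± 6.33 of ILC3-like cells in WT and 11.7% ± 8.33 in KO (SD, n = 4; exact p = 0.314).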
